A study of Homo sapiens with 12 samples.

How the data were processed

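RNA was taken from 12 subcutaneous ovarian cancer xenografts in SCID mice, 6 treated and 6 untreated. Ribosomal RNA was depleted, libraries were made with a TruSeq RNA kit and sequenced as 50 bp paired reads on a HiSeq 2000, per the labels' protocols and the series' design text. The submitters' processing notes name the aligner STAR, Partek 6.6 and the genome build hg19 without saying which step each served. Whether mouse reads were removed, the STAR version and the gene annotation are not given in the sources used here.

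The deposited table holds a value per gene and library that the authors did not name; it was taken as RPKM (reads per kilobase of transcript, scaled to library depth). This unit was inferred: in libraries with very low values those that correspond to a single read fall with transcript length. Library sums differ, but the table was filtered, so the sums do not tell RPKM from a unit with a fixed total. Transcript lengths were from GENCODE release 29, matched by symbol for 92.8% of genes, and no coordinates were taken from it. Deposited values of 0.01 and above are cut to 2 decimals. The table numbers its rows up to 21584 and holds 15785, so the authors filtered it by a rule that is not given in the sources used here. The same table gives the authors' own comparison, with an unadjusted p-value, a t score, group means in RPKM, the ratio of means and a signed fold difference; the authors' t was set against a paired statistic recomputed on the RPKM values (correlation 0.99999 across genes, largest absolute difference 0.0914). The start and stop positions, which are other columns of the deposited table, are on hg19, per the submitters' processing notes. The table names 182 genes on haplotype or unplaced contigs.

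Groups came from the labels' source names and pairs from the PDX line numbers, with 1 line per patient according to the growth protocol, so the pairing is part of the design. As a check of the pairing, the deviations of libraries from their group means were correlated: in 4 of 6 pairs the libraries correlated best with each other (r 0.744 to 0.897) and in 2 they did not (r -0.127 to 0.111). No other check of sample identity was made. A set of 19 genes on chromosome Y or of the X inactivation locus was left out of every step, and 25 symbols that had been turned into dates were not named.

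Values were analysed as log2(RPKM + 1), a scale that understates the change of low genes. Genes with at least 1 RPKM in at least 6 libraries were kept, which left 12959 and removed 2807. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend and the pair as a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count model was not used because the values are not counts. An outlined count-based test for the case of a count table was therefore replaced by limma, as laid down for normalized values. The test was tried on simulated values with the fitted levels and spreads of the 12959 genes and independent normal noise. With 200 genes changed per run in 10 runs, it made a mean of 4.6 false calls.

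Before the data were examined, 35 gene lists were fixed, covering tumour programmes and markers of other cell types or of library quality; 30 had at least 5 measured genes and were tested with camera at the preset correlation of 0.01, with estimated correlation and fry as alternatives. List means per pair were tested with an exact two-sided sign-flip test over 64 sign patterns. The rule for named genes was also fixed then. Since fewer than 3 genes passed in either direction, it took the 10 genes per direction with the smallest p among those of the same sign in 6 of 6 pairs, then up to 4 members per list with the smallest p, and ALDH1A1, PROM1 and CD44. A gene with a common inherited deletion and the class II HLA genes were not named.

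Alternatives were no block, scaling of libraries to equal medians of ratios, quantile normalization, no filter, a filter of 5 RPKM, pseudocounts of 0.1 and 0.01, limma without trend or with robust moderation, an adjusted p under 0.1, the median over list members, and leaving out each pair. Groups of 6 values were searched for outlying values with Dixon's ratio at 0.625. Tables, simulations of matched lists (10000 draws) and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. RPKM values carry no count, so no counting interval is given and precision rests on the spread over the 6 pairs. Each pair holds a single tumour per arm, so the p-values measure the spread between lines and do not separate it from the spread between tumours of a line.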

Results

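RNA sequencing was used to compare ovarian cancer xenografts that had been exposed to combination chemotherapy with untreated xenografts of the same origin. A patient-derived xenograft (PDX) is a piece of a patient's tumour that is grown in an immunodeficient mouse, here under the skin, so that tumours of the same line can be divided between treatment and no treatment. Carboplatin is a platinum drug that crosslinks DNA and paclitaxel stabilises microtubules. Treated mice received 4 weekly intraperitoneal doses of 90 mg/kg carboplatin with 20 mg/kg paclitaxel, and tumours of both arms were taken 1 week after the last dose. The series held 12 libraries, 6 treated and 6 untreated, in 6 pairs, with a single tumour per arm and line. The comparison asks which transcripts differ in the tumour that remains after chemotherapy.

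Expression was taken as RPKM for 15785 genes. The sum of RPKM per library ranged from 255186 to 329027, the median gene from 4.38 to 5.41 RPKM, and the number of genes listed at 0 from 127 to 318. In the untreated libraries the sum averaged 293386 ± 27709 (SD, n = 6) and in the treated libraries 285312 ± 11404 (SD, n = 6). Read totals were not among the values. If the unit is RPKM, the smallest values, taken as single reads, imply a depth of 20.9 to 30.7 (in 1e6 reads, median per library) in the 8 libraries that had enough of them. Host mouse cells are part of a xenograft, and the values do not separate mouse reads that align to the human genome from human reads.

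No gene passed the test across all genes, so the genes below are described by their values. The first 10 had the smallest p-values among those higher in the treated tumour of every pair. GDF15, a stress-induced cytokine of the TGF-beta family (chromosome 19, 18496968 to 18499987, hg19), averaged 10.5 ± 6.95 RPKM in untreated and 25.7 ± 20.2 RPKM in treated tumours (SD, n = 6 each), a log2 difference of 1.12 (SE 0.22). CP, which encodes the copper-carrying ferroxidase ceruloplasmin (chromosome 3, 148880197 to 148939833), averaged 48.1 ± 39.6 and 98.5 ± 71.9 RPKM, a log2 difference of 1.12 (SE 0.26). CRYAB, a small heat-shock chaperone (chromosome 11, 111779350 to 111782474), went from 65.6 ± 79.7 to 203 ± 165 RPKM, a log2 difference of 1.83 (SE 0.45). PLIN2, a coat protein of lipid droplets (chromosome 9, 19115759 to 19127605), went from 15.2 ± 3.94 to 57.8 ± 42.0 RPKM, a log2 difference of 1.51 (SE 0.41). The growth factor pleiotrophin, PTN (chromosome 7, 136912092 to 137028547), differed by 1.39 (SE 0.34). The other five of these genes were DGCR6 at 0.91, GPC4 at 1.01, the lysosomal lipid amidase NAAA at 0.65, the tyrosine kinase PTK2B at 0.60 and the early-response gene IER5 at 0.59.

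Another 10 genes had the smallest p-values among those lower in the treated tumour of every pair. HMGA2, an architectural chromatin protein (chromosome 12, 66218240 to 66360072), averaged 31.1 ± 21.0 RPKM in untreated and 10.6 ± 9.96 RPKM in treated tumours, a log2 difference of -1.47 (SE 0.42). APOC1, an apolipoprotein (chromosome 19, 45417921 to 45422607), averaged 8.06 ± 3.42 and 3.24 ± 2.37 RPKM, a log2 difference of -1.17 (SE 0.28). The keratin KRT17 (chromosome 17, 39775692 to 39780883) averaged 119 ± 110 and 60.2 ± 57.9 RPKM, a log2 difference of -0.78 (SE 0.21). The transcription factors MYB and MECOM differed by -0.56 (SE 0.16) and -0.76 (SE 0.25; MECOM at -0.50 without pair 3 and -0.35 over the 4 pairs of like libraries), and the microfibril protein MFAP2 by -0.75 (SE 0.25). EGFL8 differed by -0.78, CAPS by -0.57, CDC42EP5 by -0.53 and TMEM183A by -0.47. In pair 2 HMGA2 changed by only -0.02 and MFAP2 by only -0.04, while HMGA2 changed by -3.25 in pair 1. EGFL8 was assigned to an alternative haplotype contig of chromosome 6, so its reads could be split between copies of that region.

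**Figure D1:**
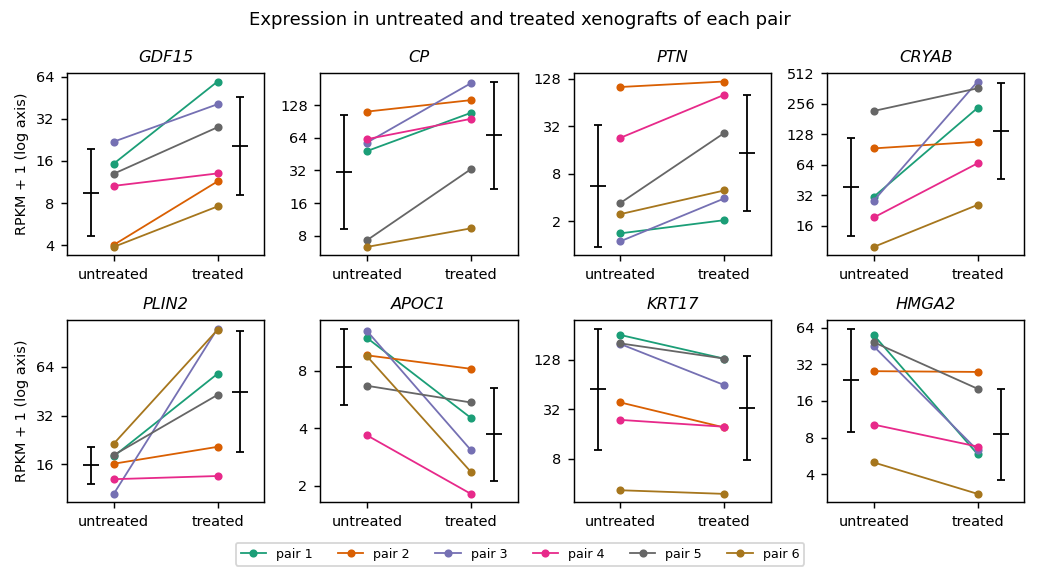
RPKM + 1 on a log2 axis for 8 genes in the untreated and treated tumour of each of the 6 pairs, with lines joining the tumours of a pair. The black bars beside the points give the mean and SD of log2(RPKM + 1) over the 6 libraries of a group. The first 5 genes were higher and the last 3 lower in the treated tumour of all 6 pairs, by amounts that ran from 0.07 to 3.91 on the log2 scale for CRYAB, PLIN2, GDF15, CP and PTN. For HMGA2 the change ran from -3.25 in pair 1 to -0.02 in pair 2.

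The test across all genes made no call. With limma and the pair as a block, 0 of 12959 genes were higher and 0 were lower in treated tumours at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 285 genes, 171 higher and 114 lower, which is 2.2% of those tested, where 648 would be expected by chance. The difference had the same sign in 6 of 6 pairs for 271 genes, 153 higher and 118 lower, or 2.09%, where chance gives 3.125%. The authors' deposited table lists 299 of its 15785 genes at a p under 0.05, and the smallest Benjamini-Hochberg adjusted value of the p-values in the authors' deposited table was 0.9365. In simulated data with the spread of these libraries the test recovered 87.3% of 4-fold, 35.5% of 2-fold and 5.67% of 1.5-fold changes. Smaller changes common to the 6 lines would therefore mostly not be detectable with this number of pairs and this spread. The spread was taken from all 6 pairs, including the 2 whose libraries did not correlate with each other. The changes were added on the log2(RPKM + 1) scale, so recovery of a given fold in RPKM is overstated for low genes. The simulated noise was normal and independent for each gene, while real genes vary together.

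**Figure D2:**
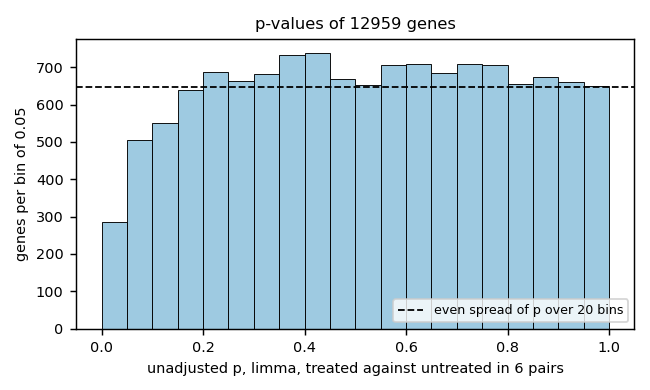
Number of genes per bin of 0.05 in the unadjusted limma p, for 12959 genes compared between treated and untreated tumours in 6 pairs; the dashed line is the 648 genes per bin that an even spread gives. The lowest bin of p holds 285 genes, fewer than any other of the 20 bins.

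Markers used for chemoresistant or tumour-initiating cells in ovarian cancer did not pass, and single pairs held opposite values. ALDH1A1, an aldehyde dehydrogenase, averaged 12.2 ± 20.2 RPKM in untreated and 15.1 ± 29.1 RPKM in treated tumours (SD, n = 6 each), with a log2 difference of -0.10 (SE 0.49), higher in 3 of 6 pairs. PROM1, which encodes CD133, differed by -0.01 (SE 1.03), with -5.50 in pair 3 and 4.43 in pair 5. The hyaluronan receptor CD44 differed by 0.50 (SE 0.76), with -3.32 in pair 3 and 3.97 in pair 5. Of the 14 measured members of the list of tumour-initiating cell markers, 1 was higher and 2 lower at an unadjusted p under 0.05. The higher one was ITGA6, at 0.48 (SE 0.18) and higher in 5 of 6 pairs. The lower ones were THY1, at -1.15 (SE 0.35), and the Wnt-linked receptor LGR5, at -1.23 (SE 0.42), each lower in 5 of 6 pairs. The list averaged -0.07 ± 0.70 (SD over the 6 pairs), and camera, limma's test of a gene list against all other genes, gave an adjusted p of 0.868. The direction of PROM1 depends on single pairs and on the pseudocount, since it was 1.09 without pair 3 and 0.09 with a pseudocount of 0.1. ALDH1A1 was at 0.41 without pair 3 and CD44 at -0.19 without pair 5. Over the 4 pairs of like libraries PROM1 was at 0.25, CD44 at 0.59 and ALDH1A1 at 0.06. In the other 2 pairs the libraries did not correlate with each other. A large value in a single pair therefore need not be a change within a line.

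Among the 23 measured p53 targets, GDF15 was the only gene that passed when adjusted over the list alone (limma adjusted p = 0.0165), and no member of the other 29 tested lists did so. Over all genes tested the count was 0 for every list. The adjustment within a list made no allowance for the number of lists, so 1 such call could arise by chance. The GDF15 call was lost without pair 1 (0.053), pair 2 (0.0823), pair 5 (0.0509) or pair 6 (0.0573), without the block (0.974) and over the 4 pairs of like libraries (0.0657). The log2 difference of GDF15 ran from 0.95 to 1.18 in these settings. The kinase gene PLK3 was higher in 5 of 6 pairs, by 0.40 (SE 0.22; 0.20 without pair 3). The p53 list as a whole averaged 0.06 ± 0.16 (camera adjusted p = 0.467), with 0.11 without pair 3 and 0.02 without pair 6. DNA repair, drug transport and survival lists did not pass over the 6 pairs either. Homologous recombination and Fanconi repair averaged -0.09 ± 0.41 (camera adjusted p = 0.103). This list was called lower without pair 2 (0.00969), without pair 4 (0.0122) and with no filter (0.0472). Its mean turned to 0.05 without pair 5 and to 0.08 over the 4 pairs of like libraries. Nucleotide excision and mismatch repair averaged -0.02 ± 0.17 (adjusted p = 0.797). Drug transport averaged 0.12 ± 0.21 (adjusted p = 0.208). It was called higher without pair 3 (0.0329), with a mean of 0.20, and over the 4 pairs of like libraries (0.0199, or 0.6 with an estimated correlation). The BCL2 family with caspase inhibitors averaged 0.05 ± 0.12 (adjusted p = 0.369), with 0.02 without pair 4 and 0.09 without pair 5. SLC31A1, a copper transporter that also carries platinum drugs, differed by 0.18 (SE 0.16; 0.11 without pair 1), and BCL2L1, an anti-apoptotic gene, by 0.32 (SE 0.17; 0.18 without pair 3). Metallothionein and glutathione genes averaged 0.13 ± 0.34 (adjusted p = 0.208), with means of 0.03 without pair 1 and 0.06 without pair 4, and were called higher without pair 3 (adjusted p = 0.0142) and over the 4 pairs of like libraries (adjusted p = 0.000251; 0.68 with an estimated correlation). Among them were GCLM, a subunit of the enzyme that limits glutathione synthesis, at 0.60 (SE 0.21) and the secreted peroxidase GPX3 at 1.80 (SE 0.65), each higher in 5 of 6 pairs. GPX3 was at 1.08 without pair 3, and its largest changes were 5.40 in pair 3 and 2.80 in pair 5. The tubulin list, which holds the targets of paclitaxel, averaged -0.01 ± 0.09 (adjusted p = 0.868).

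By camera with its preset inter-gene correlation of 0.01, 5 of the 30 tested lists were lower in treated tumours relative to other genes. All of these calls were lost when the correlation was estimated from the data. Cytosolic ribosomal proteins averaged -0.23 ± 0.42 (SD over the 6 pairs) and were lower in 4 of 6 pairs (adjusted p = 3.13e-09; adjusted p = 0.781 with an estimated correlation), with RPL8 at -0.45 (SE 0.20) and RPL28 at -0.40 (SE 0.19). Their mean was -0.13 without pair 1. RNA polymerase I and ribosome assembly genes averaged -0.16 ± 0.21 and were lower in 5 of 6 pairs (adjusted p = 1.65e-05; adjusted p = 0.689 with an estimated correlation), with the polymerase I subunit ZNRD1 at -0.48 (SE 0.19). Mitosis genes averaged -0.27 ± 0.72 (adjusted p = 2.19e-05; adjusted p = 0.781 with an estimated correlation), with cyclin B2, CCNB2, at -0.44 (SE 0.25; -0.24 without pair 5) and the kinetochore motor CENPE at -0.25 (SE 0.15). The mitosis mean rests on pair 5, where it was -1.67, and was 0.01 without that pair (adjusted p = 0.923). Cholesterol synthesis genes averaged -0.23 ± 0.28 (adjusted p = 5.27e-05; adjusted p = 0.689 with an estimated correlation), and its member IDI1, an isomerase of the pathway, was lower in 6 of 6 pairs at -0.34 (SE 0.13). Hypoxia and glycolysis genes averaged -0.25 ± 0.58 (adjusted p = 0.00118; adjusted p = 0.781 with an estimated correlation), with ANKRD37 at -0.51 (SE 0.19) and the glycolytic regulator PFKFB4 at -0.48 (SE 0.27; -0.26 without pair 4). The hypoxia mean was -0.43 without pair 2, and the call was lost without pair 3 (-0.16, adjusted p = 0.0625) or pair 4 (-0.10, adjusted p = 0.661).

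Another 8 lists were higher in treated tumours with the preset correlation, and these calls were likewise lost with the estimated one. Antigen presentation genes averaged 0.32 ± 0.69 (adjusted p = 7.13e-06; adjusted p = 0.689 with an estimated correlation). Their mean was 0.19 without pair 4, 0.15 without pair 5 and 0.50 without pair 6, and over the 4 pairs of like libraries the call was lost (adjusted p = 0.218). HLA-C averaged 192 ± 46.6 RPKM in untreated and 351 ± 214 RPKM in treated tumours (SD, n = 6 each), and its reads can be shared with near-identical genes of its family. Replication-dependent histone genes averaged 0.43 ± 0.61 (adjusted p = 1.53e-05; adjusted p = 0.689 with an estimated correlation), with HIST1H2BC at 0.88 (SE 0.28). The histone mean was 0.26 without pair 3, and over the 4 pairs of like libraries the call was lost (adjusted p = 0.529). Their transcripts lack a poly(A) tail and the members are close copies of each other. Interferon response genes averaged 0.16 ± 0.84 (adjusted p = 0.00713; adjusted p = 0.821 with an estimated correlation), with IFIT2 at 0.58 (SE 0.35; 0.22 without pair 4). The interferon mean was 0.37 without pair 5 and 0.27 without pair 6, and the call was lost without pair 3 (0.08, adjusted p = 0.218) or pair 4 (-0.11, adjusted p = 0.109). Unfolded protein response genes averaged 0.10 ± 0.28 (adjusted p = 0.0429; adjusted p = 0.781 with an estimated correlation), with the chaperone-inducing transcription factor XBP1 at 0.45 (SE 0.29; 0.14 without pair 3). That call was lost without pair 1 (0.05, adjusted p = 0.462), pair 2 (0.06, adjusted p = 0.243), pair 3 (0.05, adjusted p = 0.237) or pair 6 (0.10, adjusted p = 0.133), with no filter (adjusted p = 0.108) and over the 4 pairs of like libraries (adjusted p = 0.064). Without pair 4 the mean was 0.19.

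The remaining 4 of these 8 lists were fixed as markers of tissues next to or within a xenograft. Which cells expressed their members was not tested. Skeletal muscle markers averaged 1.02 ± 1.86 (adjusted p = 0.00207; adjusted p = 0.689 with an estimated correlation), with 4.61 in pair 4, and skeletal actin, ACTA1, was higher in 6 of 6 pairs at 2.23 (SE 0.74; 1.33 without pair 4). Without pair 4 the muscle mean was 0.31 and the call was lost (adjusted p = 0.0834). Skin epithelium markers averaged 0.75 ± 0.77 and were higher in 5 of 6 pairs (adjusted p = 0.00143, or 0.689 with an estimated correlation). Keratin 14, KRT14, was at 1.32 (SE 0.45), and at 0.84 without pair 1. The call of the skin list was lost without pair 5 (adjusted p = 0.0602). The mean of that list ran from 0.54 to 0.93 with single pairs left out. Macrophage and myeloid markers averaged 0.62 ± 1.20 (adjusted p = 0.000868; adjusted p = 0.689 with an estimated correlation), with the calcium-binding protein S100A8 at 1.43 (SE 0.60; 0.93 without pair 5). Without pair 5 the macrophage mean was 0.24 and the call was lost (adjusted p = 0.431), as it was with no filter (adjusted p = 0.163) and over the 4 pairs of like libraries (adjusted p = 0.258). Fibroblast and matrix markers averaged 0.32 ± 1.34 (adjusted p = 0.0121; adjusted p = 0.781 with an estimated correlation), but this rests on pair 5, where the mean was 2.86, since without that pair the mean was -0.19 and the list was called lower (adjusted p = 0.0282). Without pair 3 the call was lost (adjusted p = 0.14), and the mean was 0.50 without pair 2 and 0.51 without pair 4. In pair 5 the mitosis, DNA replication and Muellerian epithelial lists were at -1.67, -1.20 and -1.11. Lists with fewer than 5 measured genes were not tested against other genes: endothelial markers averaged 0.40 ± 0.75, adipocyte markers 0.92 ± 2.20, lymphocyte markers -0.10 ± 0.41 and erythroid markers -0.22 ± 1.95, and 0 mitochondrially encoded genes were measured. Without pair 5 the adipocyte mean was 0.10, the endothelial mean 0.13 and the erythroid mean -0.72. The erythroid mean turned to 0.33 without pair 2 and 0.14 without pair 6, and was -0.37 without pair 1 and -0.44 without pair 4. The lymphocyte mean was -0.02 without pair 3, -0.20 without pair 4 and 0.01 without pair 6.

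**Figure D3:**
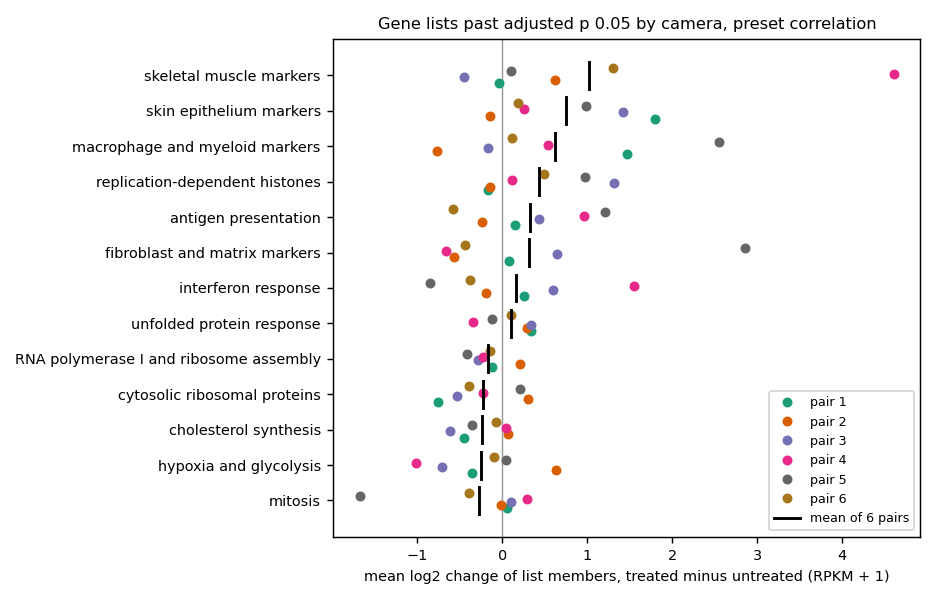
Mean log2 change of the members of each gene list, treated minus untreated on the log2(RPKM + 1) scale, with a coloured point per pair and a black bar for the mean of the 6 pairs, for the 8 higher and 5 lower lists by camera with the preset correlation. In 13 of 13 lists at least 1 pair lies on the other side of 0 from the mean, and pairs 4 and 5 hold the farthest points (4.61 for skeletal muscle and 2.86 for fibroblast markers).

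The other tested lists did not pass by camera over the 6 pairs, and several did when a pair was left out. DNA replication genes averaged -0.08 ± 0.66 (adjusted p = 0.297), with the helicase subunits MCM3 at -0.39 (SE 0.28; -0.24 without pair 3 and -0.19 without pair 5) and MCM7 at -0.37 (SE 0.29; -0.08 without pair 5). The list was called lower without pair 2 (adjusted p = 0.00225) or pair 4 (adjusted p = 0.0198) and higher without pair 5 (adjusted p = 0.0282). Muellerian epithelial markers, which mark the lineage of most ovarian carcinomas, averaged -0.11 ± 0.58 (adjusted p = 0.124). They were called lower without pair 3 (adjusted p = 0.00175) or pair 4 (adjusted p = 0.041), while their mean turned to 0.09 without pair 5 (adjusted p = 0.923). The oestrogen receptor gene ESR1 was at -0.76 (SE 0.36), and at -0.44 without pair 1. NF-kB targets averaged 0.15 ± 0.59 (adjusted p = 0.132). The member with the smallest p, NFKBIE, was at -0.35 (SE 0.17) and lower in 5 of 6 pairs. LCN2, an iron-siderophore binding protein, was at 1.25 (SE 0.64), or 0.67 without pair 3. The NF-kB list was called higher without pair 2 (adjusted p = 0.00969), pair 4 (adjusted p = 0.00487) or pair 6 (adjusted p = 0.0193). Over the 4 pairs of like libraries it was called lower (adjusted p = 0.00105, or 0.6 with an estimated correlation). Immediate early and heat shock genes averaged 0.07 ± 0.34 (adjusted p = 0.344, but called higher without pair 4 at 0.0198), with the phosphatase DUSP1 at 0.75 (SE 0.29). DUSP1 was higher in 4 of 6 pairs and ran from 0.56 to 0.94 with single pairs left out. Hedgehog, Notch and Wnt components averaged -0.02 ± 0.28 (adjusted p = 0.833), TGF-beta and EMT genes 0.03 ± 0.64 (adjusted p = 0.833, but called lower without pair 5 at 0.00122), nuclear oxidative phosphorylation genes 0.02 ± 0.31 (adjusted p = 0.700, but called higher without pair 5 at 0.0333), motile cilia genes 0.02 ± 0.50 (adjusted p = 0.797) and small structural RNAs and their host genes -0.02 ± 0.26 (adjusted p = 0.679). The mean, the median over members of their 6-pair changes and the direction in camera did not share a sign for the tumour-initiating cell, p53, immediate early, oxidative phosphorylation, TGF-beta and tubulin lists.

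Over the 6 pairs, an exact two-sided sign-flip permutation test of each list's mean gave no list its smallest possible p of 0.0312. The lowest was 0.0625, for skin epithelium markers, and the lowest Benjamini-Hochberg adjusted value over the 30 lists was 0.9. A single list at the smallest possible p could not pass that adjustment, so the absence of calls says little about any list. fry, limma's rotation test of whether a list's genes move in a common direction, also called 0 lists, with a smallest adjusted p of 0.925. Within pairs the 13 lists called by camera had estimated inter-gene correlations of 0.113 to 0.812, above the preset 0.01, so their members varied together between pairs.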

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

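The test of fibroblast markers, the repeat with a pseudocount of 0.1 and the Bonferroni adjustment below were chosen after the result was seen. Of 275 sets of 6 values searched, 17 held a value far from the other 5, and chance gives about 14. The pairs with such values were pair 3 in 5 sets, pair 5 in 4, pairs 4 and 6 in 3 each, and pairs 1 and 2 in 1 each.

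Pair 5 stood apart in 3 gene lists: fibroblast and matrix markers at 2.86, TGF-beta and EMT genes at 1.27 and mitosis genes at -1.67 (mean log2 change). Dilution of the tumour by cells that lack both sets of transcripts would lower mitosis genes and Muellerian epithelial markers alike. In that pair mitosis genes lay -0.56 (SE 0.21) from Muellerian epithelial markers, and -0.70 (SE 0.21) with a pseudocount of 0.1. DNA replication genes, at -1.20, lay near the Muellerian list at -1.11. These SEs run over genes of the same pair, and which list members the other cells express was not tested, so dilution stays open. Of the fibroblast markers 90.9% were higher by 1 or more, which restates the pattern and does not tell its sources apart, so more fibroblasts stay open. Whether all host cell types increased alike is open: endothelial (1.76) and adipocyte markers (5.0) differed by 2.74 standard errors, past the bound of 2 set beforehand, but that bound made no allowance for taking the largest of 6 differences between lists of 3 to 22 genes, and the smallest Bonferroni-adjusted p was 0.426. Over the 4 pairs of like libraries the fibroblast mean was -0.40. Mouse stromal reads aligned to human genes, a different piece of the tumour and a response to treatment in that line may each contribute, and none of these was tested. A wrong label is not excluded either.

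In pair 4 skeletal muscle markers lay far above the other pairs, with a mean log2 change of 4.61, and ACTA1 alone changed by 6.70. In pair 3 the change of BCL2L2 was 2.38, of CAPS -1.35 and of PMS1 -0.89. The change of ATP5G3 was 1.46 in pair 5.

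The remaining values far from their group were levels on the log2(RPKM + 1) scale. Among treated libraries these were BCL2L2 at 5.58 and MCM3 at 3.70 in pair 3, RPL28 at 6.94 in pair 6 and WDR43 at 4.42 in pair 1. Among untreated libraries they were IDI1 at 2.61 and MECOM at 1.89 in pair 6, and SKIL at 2.37 in pair 4. The 10 highest genes took 8.04% of summed RPKM in the treated library of pair 2, above the other treated libraries.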

How the results depend on the processing

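The alternative with the 4 pairs of like libraries was chosen after seeing the data. The count of 0 genes higher and 0 lower held in every alternative run, without the replicate block and at an adjusted p under 0.1 included. Without the replicate block 29 genes lay at an unadjusted p under 0.05, against 285 with it, and the lists called by camera stayed at 8 higher and 5 lower. The smallest adjusted p was 0.923, without pair 5. The list counts ranged from 6 to 9 higher and from 5 to 7 lower over scalings, filters, left-out pairs and the 4 like pairs, which gave 6 higher and 7 lower and 385 genes at an unadjusted p under 0.05. The lists behind these counts changed. With the preset correlation fibroblast markers went from higher to lower without pair 5 (adjusted p = 0.0282) and with the 4 like pairs (7.14e-07). DNA replication was called lower without pair 2 (0.00225) or 4 (0.0198) and higher without pair 5 (0.0282) and with the 4 like pairs (0.000285). In the last setting NF-kB (0.00105) and TGF-beta and EMT (1.97e-05) were called lower, drug transport (0.0199) and metallothionein and glutathione genes (0.000251) were called higher, and mitosis, antigen presentation, histones, macrophage markers and the unfolded protein response were not called. Endothelial markers with scaled libraries (0.0473) and adipocyte markers with no filter (0.0114) had enough genes to be tested there and were called higher. They were 0 higher and 0 lower with an estimated correlation, 0 and 0 by fry, and 0 and 0 with the 4 like pairs and an estimated correlation. Pseudocounts and limma's moderation were varied for genes only. Testing each deposited row on its own was not run, since rows are already genes, and neither were the alternatives meant for count tables.

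Of 1514 recomputed values for 109 named genes and lists, 1473 kept their direction and 41 reversed. Most of these genes were named for a shared sign in every pair or a small p, and the settings share most of their data. The share that kept its direction is therefore no measure of robustness. By limma's adjusted p for genes 0 passed the threshold, while camera with the preset correlation made the calls above. The sign-flip p of list means was not held against the threshold in these settings. With a pair left out its smallest possible value lies above 0.05 in any case. The cause of the reversals was not tested beyond the pair left out. With the 4 like pairs the reversed values were 0.050 for MCM3, 0.042 for RSPH1, 0.061 for ALDH1A1 and 0.25 for PROM1. For lists in that setting they were 0.20 for DNA replication, 0.083 for homologous recombination, 0.043 for excision and mismatch repair, -0.13 for NF-kB, -0.015 for immediate early genes, -0.26 for TGF-beta and EMT and -0.40 for fibroblast markers. Among genes with the same sign in every pair, CP was at 0.68 in that setting, PTN at 0.90, DGCR6 at 0.54, GPC4 at 0.52, MFAP2 at -0.46 and MECOM at -0.35. PROM1 was at 0.090 with a pseudocount of 0.1 and 0.13 with 0.01. With the median over members taken in each pair and then averaged, the tumour-initiating list was at 0.086 and the Hedgehog, Notch and Wnt list at 0.046.

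When single pairs were left out, ALDH1A1 ranged from -0.48 to 0.41, PROM1 from -0.90 to 1.09 and CD44 from -0.19 to 1.27. The lists whose mean crossed 0 were tumour-initiating markers (-0.29 to 0.14), Muellerian markers (-0.27 to 0.086), mitosis (-0.39 to 0.0076), DNA replication (-0.23 to 0.14), homologous recombination (-0.18 to 0.054), excision and mismatch repair (-0.064 to 0.029), tubulins (-0.049 to 0.0032), interferon response (-0.11 to 0.37), NF-kB (-0.062 to 0.25), immediate early genes (-0.016 to 0.15), Hedgehog, Notch and Wnt (-0.083 to 0.066), TGF-beta and EMT (-0.22 to 0.16), oxidative phosphorylation (-0.057 to 0.098), motile cilia (-0.10 to 0.13), fibroblast markers (-0.19 to 0.51) and small structural RNAs (-0.097 to 0.038). Leaving out pair 5 turned mitosis, DNA replication, Muellerian, homologous recombination, excision repair, NF-kB, TGF-beta and fibroblast lists. Depth is known only as an estimate, so its effect on low genes was not tested.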

Other observations

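The test with the 4 like pairs below was chosen after the result was seen. Single pairs differed from each other by more than the 6-pair averages show. In pair 4, 37 of 38 interferon response genes were higher in the treated tumour, 32 of them by 1 or more on the log2 scale (mean 1.54), while in pair 5, 33 of the 38 were lower (mean -0.85). In pair 5 the NF-kB targets averaged 1.22 and antigen presentation genes 1.21, beside markers of other cells (macrophage 2.55, fibroblast 2.86, endothelial 1.76 and adipocyte 5.0), and in pair 4 hypoxia and glycolysis genes averaged -1.02, beside skeletal muscle markers at 4.61 and adipocyte markers at 1.62. Erythroid markers, of which 4 haemoglobin genes were measured, averaged 2.27 in pair 5, -2.98 in pair 2 and -2.05 in pair 6. With a single tumour per arm in a pair, none of these values has a replicate within its line. In 2 of the 6 pairs the libraries did not correlate with each other, so a difference between pairs need not be a difference between lines.

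Swapping treated and untreated within pairs gives 32 splits, the real one included. The adjusted threshold was passed by 0 genes in the real split and by at most 0 in the others; all 32 splits reach a count of 0, so this comparison decides nothing. As many genes at an unadjusted p under 0.05 as the real 285 were found in 25 of the 32 splits, with a highest other count of 1315, and as many camera lists as the real 13 in 13 of them, with a highest other count of 16. Chance can therefore not be excluded for the number of genes at an unadjusted p under 0.05 or of lists. Of 100 splits of the 12 libraries without regard to pairs, the real one and 99 drawn at random, 99 gave, the real one included, at least the 29 genes that the real split gave without the block, and the highest other count was 2057. Most such splits part fewer pairs than the real one, and counts several times the real value point to the differences between lines.

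Fewer genes lay at an unadjusted p under 0.05 (2.2%) than the 5% that chance would give. Unlike libraries within pairs might inflate the spread, and with the 4 like pairs the share was 2.97%. That is nearer to 5% but under it, where reaching 5% was set as the sign of this cause. The SD over the 31 other splits, 1.98%, comes from fits of all pairs. Both 2.97% and 2.2% lie within 2 SD of 5%, so this SD cannot tell them from it and the question stays open. The test may be conservative on these values whatever the labels: over the 31 other within-pair splits the mean share was 3.70% (SE 0.36, from splits that are not independent), with a range of 1.54% to 10.2%. All these splits hold the unlike pairs too, so their mean share cannot tell a conservative test from an inflated spread. The conservative test stays open as a candidate explanation. A treatment effect that differs between lines was not tested.

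Ribosomal protein genes were lower in 4 of 6 pairs. Their mean log2 change of -0.23 lay outside the central 95% of 10000 lists matched on level and transcript length (-0.11 to 0.05). This does not decide on a trend with length and level. The matched genes were drawn independently, while ribosomal protein genes varied together (estimated correlation 0.528). The matched genes also had a lower median level (7.99 against 9.16 on the log2 scale). In those 4 pairs the 100 highest other genes showed 16.9% of the ribosomal protein change (-0.081 against -0.48) and were lower in 3 of them. In the other pairs both sets were higher (0.033 and 0.26). The highest genes thus fell less, but the 4 pairs were chosen by the ribosomal change itself, so a drop of all highly expressed genes stays open. With quantile normalization camera still called the ribosomal list lower (adjusted p = 0.000256 with the preset correlation). Reads shared with ribosomal pseudogenes and a response of translation genes to treatment both stay open as untested, and as the splits show, chance could give as many list calls.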
